A study of Mus musculus with 9 samples.

How the data were processed

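Poly(A)-selected RNA from cultured mouse cortical astrocytes was sequenced in 9 libraries, 3 in each of 3 groups. Per the labels' protocols, cells received 50 µM noradrenaline for 90 min, after which the medium was changed to one without the ligand. RNA was taken at 90 min in 1 treated group and 3 days after the application in the other. The unstimulated controls are titled with the 3 day time, so no control collected at 90 min was analysed here. Groups and replicate numbers were read from the sample titles. The labels do not say whether the replicates were separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

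The authors deposited a table of estimated counts per gene, with an Entrez identifier and a symbol for each of 22100 rows. Per the submitters' processing notes, fastp 0.23.4 and Salmon 1.8.0 were used with the mm39 build of the mouse genome. How transcripts were summed to genes, whether values were rounded, and the annotation release are not given in the sources used here. All deposited values were whole numbers, and rounding before the tests therefore changed none. 1 row had no symbol, held at most 0.000668% of a library's counts, and was kept under its Entrez identifier. The genome tables at hand describe an older mouse build than the one named in the notes, so no coordinates are given. Salmon shares reads between similar transcripts, so values of genes with near-identical copies or overlapping neighbours are uncertain. Whether strand was used is not given in the sources used here.

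Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 13090 genes. Library sizes were scaled with TMM factors, dispersions were estimated over all 9 libraries in 1 fit with a coefficient per group, and each pair of groups was compared with the two-sided quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p below 0.05. Every adjusted p for a gene below comes from this test. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM after TMM scaling, as mean ± SD over 3 libraries.

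35 gene lists were fixed before the data were examined, and 33 of them had the 4 or more tested members needed for a test. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. The same test with an estimated correlation, and fry, were alternatives. The 13 mitochondrially encoded genes had no row in the table, and only 3 microglia markers passed the count filter, so neither list was tested.

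The genes named were set by a rule before the data were examined. Per comparison it takes the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and group ranges that do not overlap, leaving out predicted genes and pseudogenes. It adds the 3 members with the smallest p from each of the 6 lists with the smallest camera p (cell marker and mitochondrial lists excepted), called adrenoceptors, and Igfbp2, Gfap and Fos. A gene that several parts of the rule name counts once. The rule named 33 genes at 90 min, 28 at 3 d and 33 between the times. The values of 1 gene that the rule names are not reported here. Other genes named below were chosen after their values were seen, from the fixed lists or from the called genes.

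The total count per library ranged from 15529158 to 18729980, and 3 counts, the number a count of 0 allows, corresponded to 0.158 to 0.190 CPM. Ratios for genes with few control counts carry exact 95% counting intervals, and where all 3 controls were at 0 the fold is a lower bound against 3 counts over the group. Such intervals and bounds cover counting error only. No 2 replicates matched within sampling noise: the chi-square per degree of freedom between replicates of a group ranged from 2.37 to 6.89.

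The fit was tested on simulated counts for the comparison of 3 d with control, drawn from the observed means, library sizes and dispersions, with 50 genes changed at each of 4 sizes. Over 12905 genes run, 42% of the genes changed by 0.3 on the log2 scale were recovered, 86% at 0.5, 92% at 1 and 100% at 2. Of 192 calls, 14 were of genes that had not been changed. A simulated list whose members were all shifted had an adjusted p of 1.43e-20, and 2 of the other 30 lists were also called. Genes were drawn independently of each other, so the simulation does not test the list method where members vary together. The many changed genes also ease the adjusted threshold, so recovery may be lower where fewer genes changed. Alternatives were other size factors (RLE), no or a stricter filter, DESeq2 1.42.0, a fit of only the 2 groups compared, the replicate number as a block, a fold threshold, and leaving out each library in turn.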

Results

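The data are gene-level estimated counts from 9 RNA-seq libraries of cultured mouse cortical astrocytes, the star-shaped support cells of the brain. 3 libraries came from cells collected at the end of a 90 min exposure to 50 µM noradrenaline, the transmitter of the locus coeruleus, which acts through adrenoceptors. 3 came from cells given the same exposure and collected 3 days after it, and 3 were unstimulated controls titled with the 3 day time. Totals ranged from 15529158 to 18729980 counts and 14920 to 15397 genes had at least 1 count. The first principal component held 58.4% of the variance and placed the 90 min libraries (33.7 to 36.4) apart from the controls (−18.8 to −16.6) and the 3 day libraries (−17.7 to −17.0). The cultures carried much mRNA of vimentin (Vim, 4002 ± 106 CPM in controls) and of the collagen gene Col1a1 (1419 ± 105 CPM) and little of the astrocyte filament gene Gfap (1.13 ± 0.293 CPM).

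The first comparison asks what noradrenaline changed at the end of the exposure. The orphan nuclear receptor genes Nr4a3 and Nr4a2 rose the most among the genes named by the rule. Nr4a3 (Entrez 18124) went from 7.50 ± 1.33 to 683 ± 8.72 CPM (SD, n = 3), a log2 fold change of 6.52 (SE 0.08, edgeR adjusted p = 8.78e-20). Nr4a2 (Entrez 18227) went from 4.34 ± 0.443 to 305 ± 29.0 CPM (log2 6.14, SE 0.10, edgeR adjusted p = 4.44e-18). Ramp3, which codes for a receptor activity modifying protein, rose 65.6-fold, Slc1a1, a glutamate transporter gene, 23.4-fold, the matrix protease gene Adamts1 20.9-fold and the transcription factor gene Fosb 18.4-fold. The lowest values belonged to the growth factor gene Fgf9 (Entrez 14180), which went from 13.2 ± 0.461 to 2.31 ± 0.0589 CPM (log2 −2.51, SE 0.11, edgeR adjusted p = 3.36e-12). Gpr146, an orphan receptor gene, Bmf, a pro-apoptotic BCL2 family gene, the chemokine receptor gene Cxcr4 and the homeobox gene Irx1 also fell, with log2 fold changes of −1.98, −1.94, −1.85 and −1.82. Ift80 was called at −1.86 (SE 0.40, edgeR adjusted p = 0.00132) with uneven levels, 51.7 ± 29.0 CPM in controls and 14.3 ± 10.5 CPM at 90 min, and its log2 value was −1.28 without control 1 and −2.65 without 90 min library 2.

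**Figure D1:**
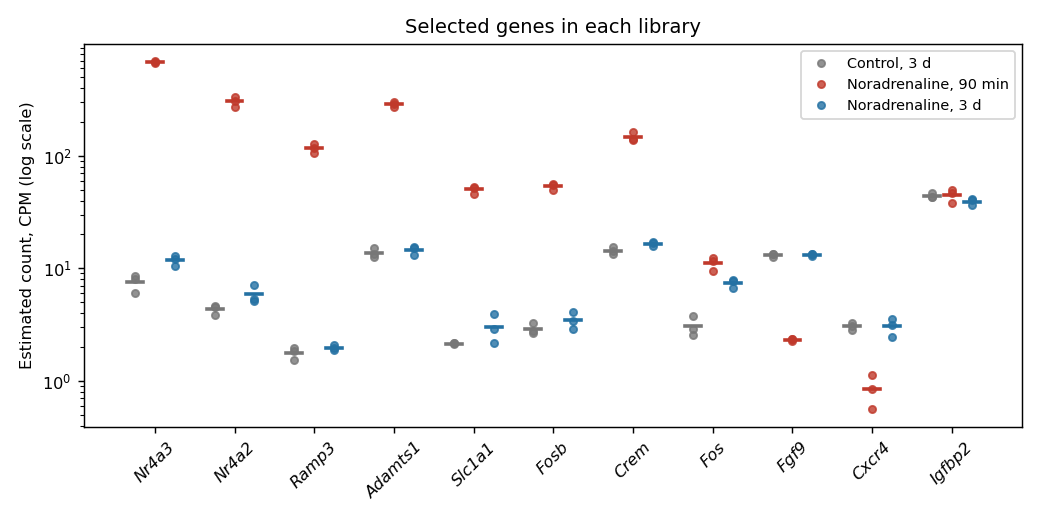
Estimated counts in CPM (log scale) of 11 named genes in each library, with 3 points per group and a line at the group mean for controls, 90 min and 3 d. Nr4a3 was at 683 CPM at 90 min against 7.50 CPM in controls and 11.8 CPM at 3 d, while Igfbp2 lay between 39.1 and 44.7 CPM on average in all 3 groups.

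Genes driven by cyclic AMP and its factor CREB rose together. Of 23 tested members of that list 21 rose, 1 fell and 1 was not called, and the same numbers were adjusted over the list alone (median log2 2.35, camera adjusted p = 3.88e-97, adjusted p = 8.73e-05 with an estimated correlation). Crem, which codes for a CREB family factor, rose from 14.4 ± 0.980 to 147 ± 12.2 CPM, and the cyclic AMP phosphodiesterase gene Pde4d from 21.9 ± 2.59 to 111 ± 3.36 CPM. Crtc2, a CREB coactivator gene, was the member that fell (log2 −0.28). Of 27 immediate early genes 16 rose and 3 fell, again with 16 and 3 adjusted over the list alone (median log2 0.55, camera adjusted p = 2.23e-19, adjusted p = 0.0112 with an estimated correlation). Maff rose from 62.2 ± 5.61 to 929 ± 50.8 CPM, Fosl2 7.58-fold and Atf3 12.1-fold. Fos itself rose 3.59-fold, from 3.08 ± 0.638 to 11.2 ± 1.47 CPM (log2 1.84, SE 0.15, edgeR adjusted p = 2.08e-08), whereas Egr1, a classical early gene, had a log2 value of −0.23 (SE 0.21, edgeR adjusted p = 0.450).

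Feedback inhibitors of MAP kinase signalling rose in 13 of 18 tested members and fell in 3, with 13 and 4 adjusted over the list alone (median log2 0.98, camera adjusted p = 6.99e-17, adjusted p = 0.00500 with an estimated correlation). The phosphatase genes Dusp1 and Dusp10 rose 7.38-fold and 5.23-fold and the receptor kinase inhibitor gene Errfi1 4.46-fold, while Dusp6 fell (log2 −0.52). Genes listed as A2-type reactive rose in 7 of 10 members and fell in 1, also when adjusted over the list alone (median log2 0.79, camera adjusted p = 2.26e-11, adjusted p = 0.00500 with an estimated correlation). Among them were the pentraxin gene Ptx3 (3.17-fold), the lipopolysaccharide co-receptor gene Cd14 (4.71-fold) and the prostaglandin synthase gene Ptgs2 (7.23-fold), which is also on the cyclic AMP list. Neurotrophic and growth factor genes rose in 14 of 27 members and fell in 4, likewise adjusted over the list alone (median log2 0.16, camera adjusted p = 2.91e-08, adjusted p = 0.0128 with an estimated correlation). Fgf2 rose 3.65-fold, Hbegf 2.58-fold and Inhba 3.68-fold, Gdnf went from 5.34 ± 0.738 to 33.0 ± 3.37 CPM, and Bdnf from 8.44 ± 0.884 to 23.4 ± 3.05 CPM. Like Ptgs2, Bdnf, Dusp1 and the immediate early gene Fosb are also on the cyclic AMP list. The calls of these lists are therefore not independent of each other.

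The extracellular matrix list was called higher (camera adjusted p = 0.0216), with 8 of 30 members risen and 0 fallen both overall and adjusted over the list alone, and had an adjusted p of 0.698 with an estimated correlation. Its median turned to −0.02 without 90 min library 3 (camera adjusted p = 0.0488). The risen members included the protease genes Adamts1 and Adamts4 (4.31-fold) and the hyaluronan synthase gene Has2 (3.59-fold), while Col1a1 had a log2 value of −0.11 (edgeR adjusted p = 0.337). Glycolysis and lactate genes rose in 12 of 25 members and fell in 1 (camera adjusted p = 0.0267, adjusted p = 0.634 with an estimated correlation), led by the hexokinase gene Hk2, from 27.5 ± 0.0419 to 181 ± 8.22 CPM. Heat shock genes rose in 8 of 14 and fell in 2 (camera adjusted p = 0.0267, adjusted p = 0.634 with an estimated correlation). NRF2 and oxidative stress genes rose in 7 of 20 and fell in 3 (camera adjusted p = 0.0223, adjusted p = 0.619 with an estimated correlation), among them Srxn1 (log2 1.81) and Slc7a11 (log2 1.66). Desensitization and cyclic AMP turnover genes rose in 6 of 20 and fell in 4, with a median of −0.07, a mean of 0.28 and a test that pointed up (camera adjusted p = 0.0450, adjusted p = 0.198 with an estimated correlation). Its median turned to 0.02 without control 2 (camera adjusted p = 0.0346). Without 90 min library 1 the adjusted p was 0.0619 for this list, 0.0575 for glycolysis and 0.0589 for heat shock, and for this list it was also 0.0576 without control 3 and 0.0832 without 90 min library 3. Adjusted over the list alone, the counts were 12 and 1 for glycolysis, 8 and 2 for heat shock, 8 and 3 for NRF2, and 6 and 4 for desensitization.

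**Figure D2:**
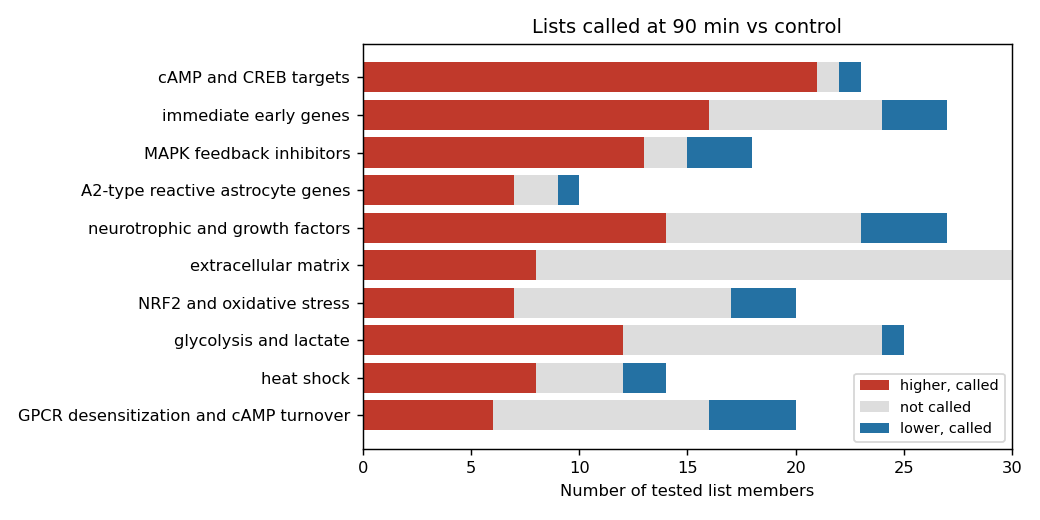
Number of tested members of each of the 10 lists called at 90 min that were called higher, called lower or not called. The cyclic AMP and CREB list had 21 of 23 members higher, against 8 of 30 for the extracellular matrix list.

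Of the receptors for noradrenaline itself, Adra1b was at 0, 1 and 2 counts in the controls and at 28, 21 and 30 counts at 90 min, a ratio of 25.3 with a counting interval of 8.35 to 125 (edgeR adjusted p = 6.72e-06). Adrb3 had a ratio of 5.66 (2.77 to 13.1, edgeR adjusted p = 0.00119), and Adra2a one of 3.73 (1.68 to 9.38, edgeR adjusted p = 0.0349). The Adra2a call was lost without control 1 (adjusted p = 0.121), control 2 (0.119) and each 90 min library in turn (0.0519, 0.0921 and 0.0582). These intervals cover counting error only, and leaving out single libraries moved the log2 values to between 3.91 and 5.39 for Adra1b, 2.17 and 3.05 for Adrb3, and 1.33 and 3.20 for Adra2a. All 3 stayed at or below 1.51 CPM. Adra1d, at 8.45 ± 0.776 CPM in controls, had a log2 value of 0.03 (SE 0.12, edgeR adjusted p = 0.876). Adra1a, Adra2b and Adra2c were too low to be tested. The list as a whole was not called (camera adjusted p = 0.556), with 3 of 6 tested members risen, and 3 risen adjusted over the list alone. Igfbp2, which codes for an insulin-like growth factor binding protein, went from 44.1 ± 2.09 to 44.7 ± 5.91 CPM (log2 0.02, SE 0.08, edgeR adjusted p = 0.861). Gfap had a log2 value of 0.41 (SE 0.27, edgeR adjusted p = 0.281).

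In all, 4320 of 13090 genes were called at 90 min, 2294 higher and 2026 lower, of which 382 and 117 changed at least 2-fold. The controls were titled with the 3 day time, so treatment and collection time cannot be separated in this comparison. Of 7 tested lists of markers of another cell type none was called at 90 min by camera, while fry called 5: neuron (adjusted p = 0.00282), ependymal (0.00313), pericyte and smooth muscle (0.00338), fibroblast and meningeal (0.00970) and neural progenitor markers (0.0449). In these 5 lists 1, 0, 1, 2 and 2 members rose and 0, 1, 2, 0 and 2 fell, of 5, 4, 7, 11 and 9. In the oligodendrocyte lineage list 1 of 6 rose and 2 fell, and in the endothelial list 1 of 6 rose and 1 fell.

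The second comparison asks what remained 3 days after the exposure. Whether the controls also had a change of medium is not given in the sources used here. An effect of that change therefore cannot be told apart from one of noradrenaline. 15 genes were called, 5 higher and 10 lower. Fos was 2.39-fold higher, at 7.43 ± 0.704 against 3.08 ± 0.638 CPM (log2 1.26, SE 0.16, edgeR adjusted p = 0.00508). Nr4a3 was 1.58-fold higher (log2 0.66, SE 0.11, edgeR adjusted p = 0.0207) and the complement gene C3 1.18-fold (log2 0.24, SE 0.04, edgeR adjusted p = 0.0207), at 271 ± 4.74 against 229 ± 9.23 CPM. The other 2, chosen after their values were seen, were Xkrx, at 3.68 ± 0.114 against 1.44 ± 0.175 CPM (edgeR adjusted p = 0.0281), and Efcab15. Efcab15 had 0 counts in each control and 23, 8 and 45 counts at 3 d (edgeR adjusted p = 0.0207).

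10 genes were lower at 3 d. The small proteoglycan genes Ogn (65.0 ± 7.23 against 88.3 ± 4.32 CPM, log2 −0.45, SE 0.06, edgeR adjusted p = 0.0162) and Fmod (log2 −0.41, edgeR adjusted p = 0.0187) fell, as did the matrix Gla protein gene Mgp (log2 −0.39, edgeR adjusted p = 0.0281). The desmosome gene Pkp1 had a log2 fold change of −0.63 (SE 0.10, edgeR adjusted p = 0.0207). The nuclear lamina gene Lmnb1 (−0.32) and the histone chaperone gene Anp32b (−0.30) both had an edgeR adjusted p of 0.0207. The remaining 4 lower genes, chosen after their values were seen, were the smooth muscle actin gene Acta2 (−0.30), the nucleolin gene Ncl (−0.23), the chaperone gene Set (−0.21) and the translation initiation gene Eif2s2 (−0.20). Igfbp2 was at 39.1 ± 2.57 CPM (log2 −0.17, SE 0.08, edgeR adjusted p = 0.530), and Gfap had a log2 value of 0.33 (SE 0.27, edgeR adjusted p = 0.768). No adrenoceptor was called.

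**Figure D3:**
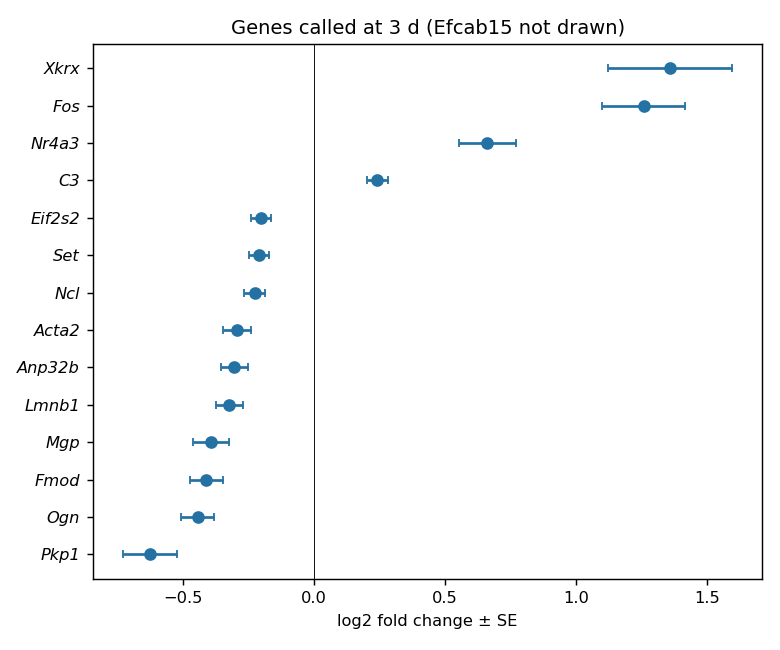
Log2 fold change (± SE) between 3 d and control of 14 of the 15 called genes, with Efcab15 left out because its controls were at 0. Fos (1.26) and Xkrx (1.36) lie farthest to the right and Pkp1 (−0.63) farthest to the left.

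Cell cycle genes were shifted down at 3 d by the preset test. The 25 genes of the G2 and M phases had a median log2 of −0.22 (camera adjusted p = 5.30e-12, adjusted p = 0.216 with an estimated correlation), with 0 called over all genes by edgeR and 11 lower when adjusted over the list alone. Their 3 smallest p-values belonged to Cdc20 (−0.42, edgeR adjusted p = 0.124), Birc5 (−0.44, 0.181) and Kif11 (−0.35, 0.299). The 24 S phase genes had a median of −0.13 (camera adjusted p = 4.19e-06, adjusted p = 0.216 with an estimated correlation), with 0 called and 4 lower adjusted over the list alone. Mcm5, Clspn and Uhrf1 had log2 values of −0.37, −0.68 and −0.29 (edgeR adjusted p 0.108, 0.176 and 0.235). Over all genes, 1221 had an unadjusted edgeR p under 0.05, where chance gives 654.5. DESeq2 called 68 genes, and 872 had an unadjusted p under 0.05 with it.

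The cyclic AMP and CREB list was shifted up at 3 d (median log2 0.12, camera adjusted p = 2.56e-06, adjusted p = 0.128 with an estimated correlation), with only Nr4a3 of 23 called, also adjusted over the list alone. Pde4b and Nr4a2 had log2 values of 0.26 and 0.45 (edgeR adjusted p 0.344 and 0.391). Interferon-stimulated genes had a median of 0.11 (camera adjusted p = 0.00120, adjusted p = 0.227 with an estimated correlation), 0 of 23 called and 1 adjusted over the list alone, with Ifit1 at 0.29 (edgeR adjusted p = 0.130), Usp18 at 0.31 (0.391) and Ifit3 at 0.14 (0.461). Genes of the unfolded protein and integrated stress response had a median of −0.05 (camera adjusted p = 0.00712, adjusted p = 0.326 with an estimated correlation), 0 of 21 called and 1 lower adjusted over the list alone, with Atf5, Psat1 and Asns at −0.20, −0.16 and −0.16 (edgeR adjusted p 0.135, 0.299 and 0.361). The extracellular matrix list had a median of −0.07 (camera adjusted p = 0.0121, adjusted p = 0.534 with an estimated correlation), 0 of 30 called and 3 lower adjusted over the list alone. Col1a1 was at 1116 ± 96.9 against 1419 ± 105 CPM (log2 −0.35, edgeR adjusted p = 0.118), Col1a2 at −0.24 (0.119) and Col5a2 at −0.20 (0.212). Pericyte and smooth muscle markers, with Acta2 the 1 called of 7 (median −0.20, camera adjusted p = 0.000923), neural progenitor markers (−0.12, 0.00712) and fibroblast and meningeal markers (−0.04, 0.0414) were also called lower, with adjusted p of 0.128, 0.178 and 0.216 with an estimated correlation. In each of these 3 lists 2 members were lower when adjusted over the list alone.

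The remaining 6 of the 15 lists called at 3 d had medians between −0.05 and 0.11. Immediate early genes (camera adjusted p = 0.0125), cytokines and NF-kB targets (0.0326), pan-reactive genes (0.0347) and A2-type genes (0.0414) were called higher, and YAP and SRF targets (0.0347) and heat shock genes (0.0378) lower. With an estimated correlation their adjusted p were 0.326, 0.216, 0.326, 0.216, 0.227 and 0.447, and none of the 15 lists was called. Adjusted over the list alone, 4 immediate early genes were higher and 1 lower, 1 pan-reactive and 1 A2-type gene were higher, 1 YAP and SRF target was higher and 2 lower, 1 heat shock gene was lower, and 0 cytokine genes passed. At the preset correlation the G2 and M, S phase, cyclic AMP, pericyte and neural progenitor lists stayed called when any 1 library was left out. Of these, fry called the cyclic AMP, pericyte and neural progenitor lists (adjusted p = 0.0439 each). It did not call the G2 and M (0.160) or S phase list (0.0884). The immediate early list was lost without control 1 (adjusted p = 0.107), the interferon list without 3 day library 2 (0.0597), the stress response list without control 3 (0.118) and 3 day library 2 (0.0597), and the matrix list without control 3 (0.242) and 3 day library 3 (0.298). The cytokine, pan-reactive, A2-type, YAP and SRF, heat shock and fibroblast lists were each lost without at least 2 libraries in turn.

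The count of 15 at 3 d depended on single libraries. Without control 1, 2 or 3 the number of called genes was 3, 0 or 3, and without 3 day library 2 or 3 it was 5 or 4. Without control 2 the smallest edgeR adjusted p was 0.0514. Leaving out 90 min library 2 or 3, which enter this comparison through the shared fit, gave 29 or 83 called genes. An unadjusted edgeR p under 0.05, held by 1221 genes with all libraries, was held by 880, 1301 and 798 without control 1, 2 and 3. Without 3 day library 1, 2 and 3 the number was 989, 897 and 1259, and without 90 min library 1, 2 and 3 it was 1186, 1302 and 1527. Fos lost its call only without control 2 among these 9 fits (edgeR adjusted p = 0.0514), and Nr4a3 also without control 1 (0.166) and 3 day libraries 2 (0.127) and 3 (0.0823).

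The third comparison asks which changes at 90 min were gone at 3 d, and it also spans the change of medium and the days in culture. Ramp3 was 59.6-fold lower at 3 d (1.96 ± 0.0977 CPM), Nr4a3 58.0-fold, Nr4a2 51.6-fold, Adamts1 19.7-fold, Slc1a1 16.7-fold and Fosb 15.3-fold. Fgf9 (5.72-fold), Bmf (3.86-fold), Gpr146 (3.83-fold), the deubiquitinase gene Usp44 (3.71-fold), Cxcr4 (3.62-fold) and Irx1 (3.30-fold) were higher. In the cyclic AMP and CREB list 20 of 23 members were lower and 1 higher (camera adjusted p = 9.21e-88, adjusted p = 0.000101 with an estimated correlation). Immediate early genes were lower in 16 of 27 members and higher in 4 (camera adjusted p = 1.22e-16, adjusted p = 0.0137 with an estimated correlation), with Maff at −3.72, Fosl2 at −2.92 and Atf3 at −3.65. The MAP kinase feedback, A2-type and growth factor lists were lower too, in 13 of 18, 7 of 10 and 15 of 27 members (camera adjusted p 3.96e-16, 9.87e-10 and 1.03e-08, and adjusted p 0.00794, 0.00794 and 0.0137 with an estimated correlation). Adjusted over the list alone the counts lower were 20, 16, 13, 7 and 15 in these 5 lists, and the counts higher were 1, 6, 5, 1 and 4.

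Of the lists called here with an adjusted p above 0.05 under an estimated correlation, interferon-stimulated genes were higher in 11 of 23 and lower in 1 (camera adjusted p = 0.00807, adjusted p = 0.467 with an estimated correlation). The extracellular matrix, heat shock, NRF2, glycolysis and S phase lists were lower (camera adjusted p 0.00196, 0.00631, 0.00763, 0.00997 and 0.0447), with 12, 8, 8, 12 and 12 members lower and 1, 1, 3, 2 and 0 higher. Their adjusted p with an estimated correlation were 0.538, 0.467, 0.467, 0.467 and 0.538. Adjusted over the list alone the counts were the same, except that 16 S phase genes were lower. The S phase call was lost without 90 min library 1 or 3 (adjusted p 0.0694 and 0.0822) or 3 day library 2 (0.070). Among adrenoceptors Adra1b and Adrb3 were lower (log2 −3.72 and −2.75, edgeR adjusted p 1.14e-05 and 0.000453), with Adrb3 at −3.56 without 3 day library 2. Fos was lower at 3 d than at 90 min (log2 −0.59, SE 0.13, edgeR adjusted p = 0.00179). Igfbp2 had a log2 value of −0.19 (SE 0.08, edgeR adjusted p = 0.0644), which became −0.29 (edgeR adjusted p = 0.00143) without 90 min library 3. Of 13090 genes 5110 were called, 2442 higher and 2668 lower.

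The changes from control at the 2 times overlapped in few called genes. Fos, Nr4a3 and Efcab15 were higher at both times, where independent lists would share 0.876, and Set was lower at both, where 1.55 would be shared. Lmnb1 and Eif2s2 were higher at 90 min (log2 1.95 and 0.15) and lower at 3 d, where 2.53 opposite pairs would be expected. Across genes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson correlation of 0.263 and a covariance of 0.0304. In 100 simulations of unchanged groups that share their controls, with the controls drawn as well, the correlation averaged 0.514 and the covariance 0.0153 (highest 0.0202), so sharing alone gives a positive covariance. The observed covariance was higher than the simulated mean by 0.0151. Genes with extreme values at both times weigh heavily on a covariance, such as Efcab15, with log2 values of 7.66 at 90 min and 7.59 at 3 d. The excess may therefore rest on few genes. Unchanged groups yield few calls, with 0.16 genes higher and 0.1 lower at both times on average. The 3 controls are too few to split, so part of the excess in calls may come from the shared controls.

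**Figure D4:**
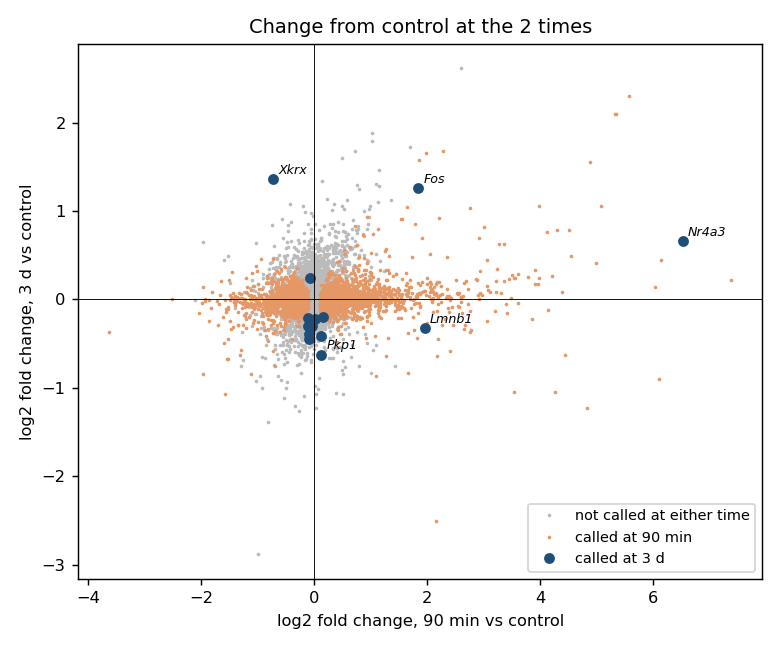
Log2 fold change from control at 90 min (horizontal) and at 3 d (vertical) for the tested genes with counts in all 3 groups, coloured by whether a gene was called at neither time, at 90 min or at 3 d. Genes called at 3 d are larger points, of which those that lie apart are labelled, with Fos at 1.84 and 1.26 and Lmnb1 at 1.95 and −0.32.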

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

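The tests of explanations in this part, the counts over splits included, were written down after the results were seen, while the comparison of 3 d with 90 min was planned. The change from control differed between the 2 times, by the test of 3 d against 90 min itself, for 5110 of 13090 genes. Of the 58 genes set by the naming rule 53 differed, a share the rule itself makes high, because it picks genes called in that comparison. 2 genes called at both times with opposite signs differed as well: Lmnb1 by −2.28 (SE 0.05, edgeR adjusted p = 6.98e-17) and Eif2s2 by −0.36 (SE 0.04, edgeR adjusted p = 5.50e-07) on the log2 scale.

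Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many called genes (4320 at 90 min, 15 at 3 d, 5110 between the times). The highest number from another split was 1. Those other splits mix libraries of both groups, so a real difference widens their spread and lowers their calls. The low number is therefore no measure of how many calls arise without a difference.

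Fos and Nr4a3 were above control 3 days after the exposure. Reads or RNA carried over from the 90 min libraries would leave the same share of every strong rise. Apart from Nr4a3, 88 called genes had a log2 rise above 2.5, and they kept a pooled 0.599% (95% interval 0.432 to 0.767). Fos, with a smaller log2 rise of 1.84, kept 53.9% (37.2 to 70.5), which argues against carry-over for it. However, 1 of the 88 kept a larger share: Efcab15, also called at 3 d and at 0 counts in the controls, kept 94.6% (42.3 to 147). Nr4a3 kept 0.632% (0.432 to 0.831), as much as the pooled share, so carry-over and a small lasting rise could both give its value. The shares of the 88 genes were not all alike, with a median of 0.961%. Vdr kept 1.70% (0.819 to 2.59) and Lhfpl2 3.51% (1.69 to 5.33), while Vgf kept 0.103% (−0.354 to 0.560). The match of Nr4a3 with the pooled share is therefore no evidence for carry-over. For Fos, a stimulus close to collection remains open. The 26 other immediate early genes of the list had a median log2 of 0.036 at 3 d, between −0.34 and 0.42. The median was 0.26 for the 5 used at first, Egr1, Egr2, Ier2, Junb and Zfp36. This decides neither way, because only a median below 0 by more than the genes' spread was set to count against a stimulus. Cells without a stimulus would not give such a median.

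Nefl and Slc32a1, neuronal genes on the list of markers fixed beforehand, had 0 counts in all 3 controls and 61 and 41 counts over the 90 min group. Of the other 14 markers, Gad2 (3 to 27 counts), Gad1 (0 to 6), Tubb3 (18 to 48) and Nefm (25 to 49) had more counts too, without a call. Only 5 of the 16 markers passed the count filter, so a missing call can also mean that a gene was not tested. Stmn2 (52 to 38), Slc17a7 (8 to 6), Elavl3 (5 to 3), Dcx (2 to 0) and Rbfox3 (1 to 0) had fewer. The list (median log2 0.90) was called by fry (adjusted p = 0.00282) but not by camera (0.574). Neurons would bring all their abundant transcripts, and the 13 other markers without Map2, summed in place of Snap25 (3 to 5), Syt1 (1 to 3) and Stmn2 (52 to 38), used at first and picked after their values were seen, gained 69 (118 to 187). Against the 102 of Nefl and Slc32a1, themselves chosen for their 0 counts in controls, this differs by −33 (95% interval −72.5 to 6.54, from counting error alone, without depth or the spread between libraries), which decides neither way. Depth is too small a cause, at 1.09 times the controls' total against a Nefl at least 19.6-fold higher after scaling, while neurons in the 90 min cultures stay open, beside induction in the cultured cells, which may be a response to noradrenaline or to the earlier collection, and which the design does not separate.

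Ogn, Fmod, Mgp and Acta2 were lower at 3 d (median log2 −0.40), and fewer fibroblast-like cells would lower their other markers alike. The 11 tested fibroblast and meningeal markers had a mean of −0.098 (95% interval −0.204 to 0.009, which takes the genes as independent). The value −0.40 comes from genes picked because they were called lower here, so it may be too large a yardstick. The gap between these values therefore does not decide whether such a loss is the whole cause. Of the 11 markers, the 4 collagens had log2 values of −0.35 to −0.21 without a call, while the other 7 lay between −0.15 and 0.11. The list was called lower (camera adjusted p = 0.0414), so a partial loss could still add to the fall. The test took this form after 2 others on the 7 alone, the first of which also required those 7 to differ from each other, which they did not. The median of Ogn, Fmod, Mgp and Acta2 was between −0.39 and −0.41 without each control, with −0.391 the smallest. No gene, though, was called without control 2. These genes were picked among those called with all 3 controls, which favours genes with even controls. The median therefore does not decide whether a single control that stands apart gave the calls. A lasting response of the matrix-producing cells to noradrenaline, or to the change of medium, is a hypothesis that these libraries leave untested.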

How the results depend on the processing

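All alternatives were set before the data were examined. No called gene named by the rule turned its sign. The median, near 0, of 2 called lists at 90 min did: desensitization to 0.02 without control 2 and extracellular matrix to −0.02 without 90 min library 3, both still called. At 90 min 4320 calls and between the times 5110 stayed within 1.5 times under every alternative but a log2 threshold of 1 (499 and 516). Leaving out a library gave 3534 to 4494 and 4266 to 5319. At 3 d the 15 calls became 205 with no filter, 68 with DESeq2 (11 shared), 76 in a fit of only the 2 groups (14 shared), 3 at a log2 threshold of 1, and 0 to 83 without a library. The 4 genes changed alike at both times became 15 with DESeq2, 1 at an adjusted p of 0.01 and 0 to 19 without a library. With an estimated correlation the called lists fell from 10, 15 and 11 to 5, 0 and 5 (90 min, 3 d, between the times), and with fry, which tests the list's own genes, they were 25, 5 and 26. Without a library they were 7 to 10, 9 to 15 and 10 to 11. The cause of these shifts was not tested. Adra2a lost its 90 min call in 5 fits without a library and under the block, and it was the only gene named by the rule at 90 min to do so. At 3 d the genes named by the rule lost 39 calls, counted per gene and per fit, over the 9 fits without a library, Fos only without control 2 (edgeR adjusted p = 0.0514). DESeq2 gave Fos and Mgp no adjusted p, and genes without one count as not shared. No other called gene named by the rule lost its 3 d call with DESeq2. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between −0.148 and 0.049 (9 pairs, 0 over 0.1), and 0 of 9 libraries correlated best with its own number. A fit with the number as a replicate block called 3907, 3 and 4662 genes, 10, 15 and 11 lists, and left 1 gene changed alike at both times. Depth limits the adrenoceptors and the genes at 0 counts, where 3 counts correspond to up to 0.190 CPM.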

Other observations

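The list tests in this part were planned, and the genes named in it were chosen after their values were seen. Several lists without a call at 90 min held genes that changed in both directions. Interferon-stimulated genes fell in 8 of 23 members and rose in 1 (camera adjusted p = 0.0812), with the transcription factor gene Irf1 from 30.6 ± 2.19 to 12.7 ± 0.357 CPM and Ifit3 at a log2 of −0.55. Cytokine and NF-kB target genes rose in 10 of 18 and fell in 2 (camera adjusted p = 0.108): the chemokine gene Cxcl1 rose (log2 2.05) while Nfkbia, which codes for the NF-kB inhibitor, fell (−1.19). Astrocyte identity genes fell in 10 of 23 and rose in 2 (camera adjusted p = 0.0905), with Sox9 from 248 ± 6.59 to 141 ± 1.84 CPM, Id3 from 252 ± 8.52 to 125 ± 12.2 CPM, and the gap junction gene Gja1 higher (55.5 ± 5.39 to 106 ± 3.20 CPM). Clock genes rose in 4 of 19 and fell in 8 (camera adjusted p = 0.858): Per1 (log2 2.07) and Nfil3 (2.53) rose, and Nr1d1 (−1.21) and Dbp (−0.72) fell. Cholesterol synthesis genes rose in 7 of 24 and fell in 7 (camera adjusted p = 0.556), with Mvk at 1.39 and Pmvk at 1.70. In the IGF axis (3 of 12 higher, 2 lower, camera adjusted p = 0.969) the insulin receptor substrate gene Irs1 fell from 76.1 ± 4.50 to 23.1 ± 2.32 CPM.

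Among the tested genes, 4 with 0 counts in every control had at least 10 counts in each 90 min library, as did Slc32a1 (13, 10 and 18 counts), which was too low to be tested. Beside Nefl (at least 19.6-fold higher against 3 counts over the control group) they were the uncoupling protein gene Ucp1 (27, 25 and 30 counts, at least 26.3-fold), Zdbf2 (at least 41.0-fold) and Efcab15 (at least 24.0-fold). Gvin1, a member of a family of similar genes, went the other way, with 53, 61 and 36 counts in controls and 0 in all 90 min libraries, and reads shared within the family leave its value uncertain. Wnt9b went from 2 to 168 counts over the group (ratio 80.8, interval 22.0 to 672), and the homeobox gene Dlx5 from 6 to 126 (20.2, 9.02 to 56.1). The neuropeptide precursor gene Vgf went from 14 to 2489 counts (171, 102 to 313).

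The remaining lists were not called at 90 min. Of them, glycogen metabolism genes rose in 2 of 22 and fell in 5 (camera adjusted p = 0.615), pan-reactive genes in 2 and 2 of 12 (0.786), A1-type genes in 2 and 2 of 12 (0.858), and genes of glutamate, GABA and potassium handling in 3 and 2 of 12 (0.556). Synapse modulators rose in 4 and fell in 1 of 18 (0.858), YAP and SRF targets in 5 and 7 of 19 (0.913), and stress response genes in 6 and 3 of 21 (0.913). S phase genes rose in 8 and fell in 0 of 24 (0.445), and G2 and M genes rose in 2 and fell in 0 of 25 (0.969, with a median of 0.04 and a test that pointed down). Adjusted over the list alone the counts in this part were the same, except 10 lower clock genes, 0 lower synapse modulators and 1 higher G2 and M gene. The YAP and SRF, cholesterol, clock, stress response, endothelial, fibroblast, pericyte and ependymal lists had a median and a mean of different sign, or a mean against the direction of the test. Marker lists gave camera adjusted p of 0.913 for oligodendrocyte lineage, 0.574 for neurons, 0.858 for endothelium, 0.786 for fibroblasts and meninges, 0.445 for pericytes and smooth muscle, 0.203 for ependyma and 0.913 for neural progenitors.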
